A study of Mus musculus with 2 samples.

How the data were processed

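Each array was a two-colour Agilent array read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers. The deposited scanner files hold the intensity of each spot and of its local background in a green (AlexaFluor555) and a red (AlexaFluor647) channel, not yet normalized. They also hold processed intensity signals that the software had background-subtracted and dye-normalized with a LOWESS curve, per the file headers. A deposited value table holds 1 signed fold per probe and array, positive for a ratio above 1 and negative for the inverse. How it was made is not given in the sources used here. Set against the scanner files' processed signals over probes well above background in both channels, its log2 values had correlations of 0.982 and 0.985 once the dye-swapped array was turned, and of 0.576 and 0.456 over all 39396 matched probes. This settled its direction as labelled knockout over control. Its median was 1 in both columns, 33.7% and 34.1% of its values were exactly 1, and its floor and centring stay unknown.

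Mean spot intensities were corrected with normexp (offset 50) against the median local background, and normalized by loess within each array, with control spots and a filler probe given weight 0. Spots marked as non-uniform (186 on the female and 223 on the male array) were left out, the 4 spots of a probe were averaged, and each log2 ratio was turned to labelled knockout over control. The median SD between the spots of a probe was 0.0693 and 0.0630 log2 units. Probes were kept where more than 0.5 of their spots were well above background in the knockout channel of both arrays or in the control channel of both arrays, which left 25934 of 39396 probes. Both arrays were on 1 slide and in 1 scan, so these could not act as a batch between them.

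Accessions in the files were paired with symbols through a RefSeq gene table of assembly GRCm38.p6, used for names and for the order of neighbouring genes. It named 28328 probes, and 11101 kept the name in the file. The genome build behind the array design is not given in the sources used here, so no coordinates are printed. For genes with several probes the brightest was used. When each probe was counted by itself, 25 genes had a called probe and probes on both sides of 0.

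Log2 ratios were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) and Benjamini-Hochberg adjustment over 20629 genes. There was 1 residual degree of freedom and a prior of 5.24, so p-values lean on the spread pooled across genes. Pairs are separate samples by their labels, but whether each RNA came from 1 embryo or a pool is not given in the sources used here. Errors are SDs over the 2 pairs. Of 32 gene lists fixed before the data were examined, 29 were tested with cameraPR on the moderated statistics (preset correlation 0.01, two-sided). The other 3 (the targeted genes, the sex-linked genes and the genes the study picked) are given as values. With an estimated correlation, 0 lists passed, but that test rests on the 1 residual degree of freedom and cannot decide whether a list shifted.

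Named genes were chosen by a rule also fixed before the data were examined. It took Tbx2, Tbx3 and Tbx18, the 12 largest rises and 12 largest falls among genes past the threshold with the same sign in both pairs (standard symbols only, without sex-linked genes), Dkk2, Shisa2, Bmper, Cxcl12, Foxf1 and Bmp4, and up to 4 members of each list, or the 2 with the largest mean change where none passed. The value of 1 gene that this rule takes is not reported here.

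The procedure was tested on simulated spot intensities for the comparison of labelled knockout and control, with 20629 genes in the fit, 200 of them changed by a set fold, the 22 genes of 1 list shifted and an intensity-dependent dye bias added. Of genes changed 1.5-fold, 76.1% were called, and of those changed 2-fold or 4-fold 100% were called. Of 20407 unchanged genes, 7 were called, which is 3.48% of all calls, and of 29 lists the 1 that was shifted passed and 0 of the others did. The simulated spread was drawn from the fitted prior, so the test does not cover a poor fit of that prior. Noise was drawn for each gene independently, and the dye bias depended on intensity alone. The test therefore does not cover correlated genes, which matter for list calls, or dye effects on single genes.

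Alternatives were no background subtraction, the processed signals, the median of pixels, median centring, scaling between arrays, the deposited value table, other filters on dim probes, outlier spots kept, other ways to join probes, other variance models, other thresholds, other list tests and each replicate left out.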

Results

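Gene expression was compared between ureters of E14.5 mouse embryos that, by their label, lack the T-box transcription factors Tbx2 and Tbx3 in the ureteric mesenchyme, and control ureters. The deletion used floxed alleles of both genes and Cre recombinase expressed from the Tbx18 locus, which is active in the progenitors of the ureteric mesenchyme. The controls carried no Cre allele, and 1 of their alleles of Tbx2 and of Tbx3 is not specified by the label. The data were 2 two-colour arrays, each holding 1 labelled knockout and 1 control RNA. Replicate 1 was a female pair with the knockout RNA in AlexaFluor647, and replicate 2 was a male pair with the dyes exchanged, so sex and dye orientation cannot be told apart. How many embryos went into each RNA is not given in the sources used here. With n = 2 pairs, the number of arrays limits the precision of every value.

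On both arrays 39429 probes were measured with 4 spots each. In the green channel 70.8% of spots were well above background in the female pair and 71.6% in the male pair, against 66.9% and 64.3% in the red channel, and 0 spots were saturated. Xist, the RNA of the inactive X chromosome, had a mean log2 intensity of 12.49 in the female pair and 6.35 in the male pair, and the Y-linked Ddx3y had 6.34 and 13.40. Both RNAs of each pair showed the sex given by the label.

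The targeted genes were examined first. Tbx3 was lower in the ureters labelled knockout, with a log2 fold change of -1.09 ± 0.10 (SD, n = 2 pairs, adjusted p = 0.000862). Tbx2 was higher, at 0.86 ± 0.12 (SD, n = 2 pairs, adjusted p = 0.00236), and rose in both pairs. The Tbx2 value goes against the label at the level of this transcript. Whether either probe lies inside the deleted part of its gene is not given in the sources used here, and a probe outside that part would check nothing. Directions below are therefore those of the ureters labelled knockout against control. Tbx18, whose locus carries the Cre, had a log2 fold change of 0.15 ± 0.0011 (SD, n = 2 pairs), which did not pass (adjusted p = 0.379).

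Of 20629 genes tested with limma, 385 were higher and 374 were lower in the ureters labelled knockout at an adjusted p under 0.05, which is 3.68% of the genes tested. By size alone, 43 genes were at least 2-fold higher in both pairs, 51 were at least 2-fold lower in both pairs, and 0 were changed at least 2-fold in opposite directions. The log2 fold changes of the 2 pairs had a Pearson correlation of 0.606 and a Spearman correlation of 0.267 across genes, which are not independent replicates, and the Pearson correlation was 0.265 with median centring in place of loess. The counts depended on normalization. With median centring, 114 genes were higher, 128 were lower and 6 were at least 2-fold apart in opposite directions. With the deposited values, 142 genes were higher and 143 lower. Of 73 named genes past the threshold, 38 lost the call under 1 or more alternatives. The 35 that kept it comprise the largest rises and falls other than Gbp2b, and Tbx2, Tbx3, Dkk2, Lgr5, Wnt11, Fst, Col8a1, Spon1, Cyp26a1, Hey2, Fabp7 and Prph. The p-values rest on the spread between these samples, mostly as pooled across genes, and measure no spread beyond these samples.

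**Figure D1:**
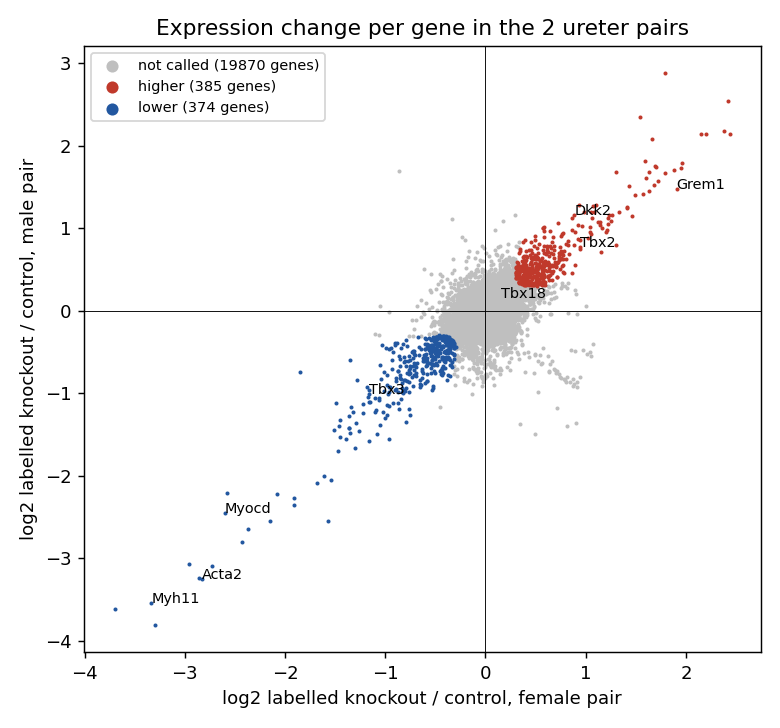
Each point is 1 of the 20629 genes, with its log2 labelled knockout over control value in the female pair on the x axis and in the male pair on the y axis. Red points are the 385 genes higher and blue points the 374 genes lower at an adjusted p under 0.05, and Myh11, Acta2 and Myocd lie far into the lower left quadrant.

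Of the 29 lists tested, smooth muscle had the largest median change. Of 22 measured members of the smooth muscle list, 15 fell, 1 rose and 6 did not pass. Actg2, the smooth muscle gamma actin, had a log2 fold change of -3.55 ± 0.36 (SD, n = 2 pairs), the smooth muscle myosin heavy chain Myh11 -3.44 ± 0.15, calponin Cnn1 -3.05 ± 0.27 and the smooth muscle alpha actin Acta2 -3.04 ± 0.29, with adjusted p-values from 3.62e-05 to 0.000105. Transgelin (Tagln) fell by 2.62 on the log2 scale, cardiac troponin Tnnt2 by 2.14 and Myocd, a transcriptional coactivator of smooth muscle genes, by 2.53. The member that rose was Pcp4, a calmodulin-binding protein, at 0.63. Desmin (Des), at -0.079, and Smtn, at -0.12, did not pass. Pcp4, Des and Smtn were chosen for naming after their values were seen. The list's median was -0.88 (cameraPR, adjusted p = 9.84e-129 with the preset correlation, adjusted p = 0.784 with an estimated correlation). Adjusted over the list alone, 17 members were lower and 1 higher. The median was -0.44 when each probe was counted by itself. In the same ureters the median of the list of neural crest, glia and neurons was 0.28, that of endothelium 0.19, that of immune cells 0.15, that of immediate early and heat shock genes -0.33, and that of 9 non-coding RNAs without a poly(A) tail, a list made after the data were examined, -0.50.

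**Figure D2:**
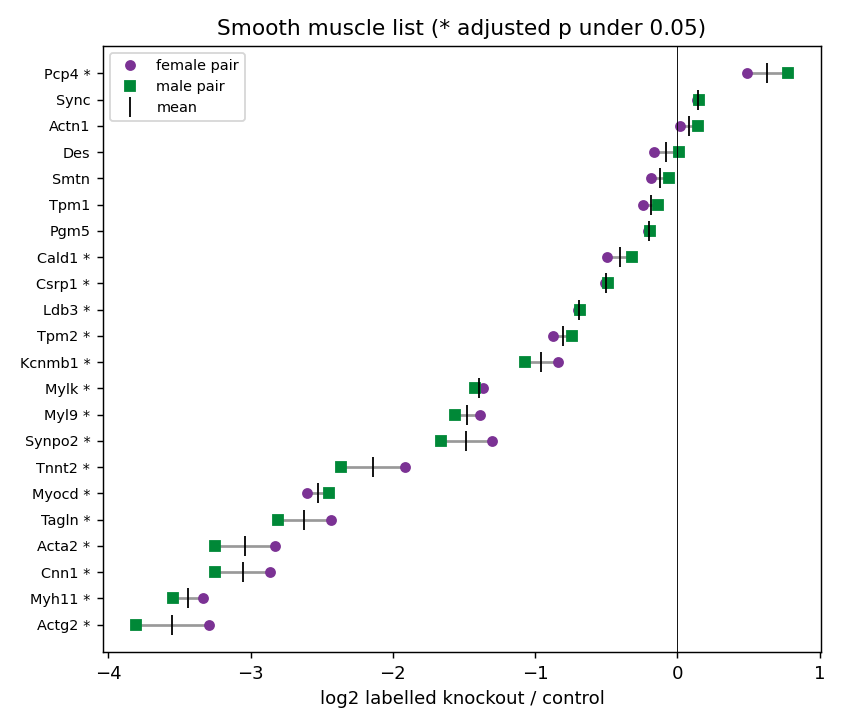
Log2 labelled knockout over control of the 22 measured genes of the smooth muscle list, in the female pair (circles) and the male pair (squares), with the mean as a vertical tick. Actg2, Myh11, Cnn1 and Acta2 lie at -3.04 or lower on average, while Des and Smtn lie close to 0.

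Other genes among the 12 largest falls were C1ql3, a secreted C1q-like protein, at -3.66 ± 0.053 (SD, n = 2 pairs), Fbxl22, an F-box protein of the sarcomere, at -3.02 ± 0.083, and the homeobox gene Alx1 at -2.92 ± 0.26. Colq, the collagen-like tail of acetylcholinesterase, was at -2.39 ± 0.26, and the carbonic anhydrase Car3 was at -2.35 ± 0.29. Adjusted p-values of these 5 genes were between 2.61e-05 and 0.000237. A dimmer probe for Fbxl22 gave -0.65, and a dimmer probe for Colq gave -1.01, so the sizes of these falls differ between probes.

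The 12 largest rises included members of a pair of gene families whose copies are similar in sequence, so that signal may be shared among them. Of 8 major urinary protein genes measured, a group put together after the data were examined, 7 rose, with Mup1 at 2.48 ± 0.088 (SD, n = 2 pairs), Mup18 at 1.79 ± 0.12 and Mup19 at 1.65 ± 0.11. The control channel was well above background for Mup1 and Mup18 on 1 of 2 arrays. With the scanner software's processed signals, Mup1 was at 4.06, Mup18 at 3.35 and Grem1 at 2.87. Of 10 guanylate-binding protein genes, grouped in the same way, 4 rose (2 with the deposited values) and 6 did not pass, with Gbp2b at 2.33 ± 0.77, Gbp3 at 1.87 ± 0.29 and Gbp2 at 1.70 ± 0.16. The Gbp2b call ended with the deposited value table and with robust eBayes, and its adjusted p ranged from 0.000282 to 0.210 over the alternatives. The other rises were Tmem229a at 2.29 ± 0.21, Cox8b, a subunit of cytochrome c oxidase, at 1.87 ± 0.12, Gabra2, a GABA receptor subunit, at 1.72 ± 0.042, the neural adhesion protein Lsamp at 1.72 ± 0.024, the BMP antagonist Grem1 at 1.69 ± 0.31 and the cytochrome P450 Cyp2e1 at 1.60 ± 0.0042. For Grem1 the control channel was also well above background on 1 of 2 arrays.

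The study is known to have picked Dkk2, Shisa2, Bmper and Cxcl12 from these samples, so their directions here are not independent evidence. The same holds in part for lists that contain them, such as WNT antagonists (Dkk2 and Shisa2) and chemokines and receptors (Cxcl12). Of these 4 genes, 3 rose over all genes tested. Dkk2, a secreted modulator of WNT signalling, had a log2 fold change of 1.02 ± 0.19 (SD, n = 2 pairs, adjusted p = 0.00209). Shisa2, an antagonist of WNT and FGF receptor maturation, was at 0.56 ± 0.11 and the BMP-binding protein Bmper at 0.43 ± 0.0082. The chemokine Cxcl12, at 0.21 ± 0.029, did not pass (adjusted p = 0.188). Adjusted over these 4 genes alone, 4 were higher. Since the study picked them from these samples, that count is no added evidence, for Cxcl12 or the others. Foxf1, a transcription factor of the mesenchyme, was at -0.49 ± 0.11 (adjusted p = 0.0181), and the ligand Bmp4 at 0.36 ± 0.026 (adjusted p = 0.0426). The calls of Shisa2, Bmper, Foxf1 and Bmp4 ended under 3 or 4 of 13 alternatives each, with no change of direction.

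Several signalling lists were shifted upwards, beside the shifts of neural, endothelial and immune markers given with the smooth muscle genes. Among 13 BMP antagonists, 4 rose, 1 fell and 8 did not pass. Fst, which binds activins, was at 1.30 ± 0.22 (SD, n = 2 pairs) and Sostdc1, which antagonises both BMP and WNT signals, at -0.50 ± 0.097. The median of that list was 0.16 (adjusted p = 2.05e-06, and adjusted p = 0.784 with an estimated correlation), and adjusted over the list alone 6 were higher and 1 lower. Among 11 chemokines and receptors, 3 rose and 8 did not pass. Ackr3, a scavenging receptor of Cxcl12, was at 0.54 ± 0.0027, Cxcl14 at 0.44 ± 0.033 and Ccl11 at 0.34 ± 0.011. That list had a median of 0.21 (adjusted p = 7.73e-05, and adjusted p = 0.784 with an estimated correlation), with 9 higher adjusted over the list alone. It contains Cxcl12, which the study picked from these samples, so its shift is not fully independent of that choice. Among 11 WNT ligands and R-spondins, 2 rose and 9 did not pass, with Wnt11 at 0.69 ± 0.11 and Wnt5b at 0.44 ± 0.058. The median was 0.17, or 0.11 without a filter on dim probes (adjusted p = 0.00449, and adjusted p = 0.784 with an estimated correlation), with 3 higher adjusted over the list alone.

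Markers of other cell types were measured in the same way. Of 18 genes of neural crest, glia and neurons, 6 rose and 12 did not pass. The glial fatty-acid-binding protein Fabp7 was at 0.71 ± 0.023 (SD, n = 2 pairs), Hand2 at 0.70 ± 0.28, peripherin (Prph) at 0.69 ± 0.071 and dopamine beta-hydroxylase (Dbh) at 0.62 ± 0.32. The median was 0.28 (adjusted p = 4.90e-08, and adjusted p = 0.784 with an estimated correlation), and 11 were higher adjusted over the list alone. The endothelium list, with a median of 0.19, passed as a set (adjusted p = 0.00497, and adjusted p = 0.784 with an estimated correlation), although 0 of its 14 genes passed over all genes tested and 6 were higher adjusted over the list alone. Its members with the largest mean values were Egfl7 at 0.32 ± 0.75 and Kdr at 0.30 ± 0.094. The immune list also passed as a set, with a median of 0.15 (adjusted p = 0.0118, and adjusted p = 0.784 with an estimated correlation), while 0 of 14 genes passed and 2 were higher adjusted over the list alone. There Lyz2 was at 0.32 and Ptprc at 0.29. Urothelium, the epithelium of the ureter, had a median of -0.014 (adjusted p = 0.786) and 0 of 22 genes passed, with Upk1b at -0.29 and Upk3a at 0.27.

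Immediate early and heat shock genes, which respond to handling of tissue as well as to signals, were shifted downwards. Of 15 genes, 5 fell and 10 did not pass, with Fosb at -0.97 ± 0.53 (SD, n = 2 pairs), Atf3 at -0.73 ± 0.44, Fos at -0.72 ± 0.38 and Egr1 at -0.70 ± 0.35. The median was -0.33 (adjusted p = 0.000138, and adjusted p = 0.784 with an estimated correlation), and 9 were lower adjusted over the list alone. The fall was larger in the female pair, with a list median of -0.38, than in the male pair, with -0.14, and this difference was not tested. The calls of Fosb, Atf3, Fos and Egr1 each ended with the processed signals of the scanner software, the deposited value table, median centring and robust eBayes. Atf3 lost its call under further alternatives, 7 of 13 in all.

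The remaining 21 lists did not pass as sets. Adjusted over the list alone, some of them also had called members. Other extracellular matrix had 10 higher and 5 lower, erythroid genes 4 higher, and cartilage 2 higher and 4 lower. Proliferation and urothelium had 0. Counts adjusted over a list alone therefore do not set apart the lists that passed. Ureteric mesenchyme transcription factors had a median of -0.11 (adjusted p = 0.113), or -0.20 with each probe counted by itself, with Foxf2 at -0.61 ± 0.0014 (SD, n = 2 pairs; -0.95 with the deposited values) and Osr1 at 0.43 ± 0.11 among its called genes. WNT targets and feedback genes had a median of -0.027 (adjusted p = 0.335), while the set test pointed upwards, and Lgr5, at 1.00 ± 0.048, and Lef1, at 0.57 ± 0.040, rose. WNT antagonists had a median of 0.042 (adjusted p = 0.216), with Dkk1 at 0.51 ± 0.20. BMP ligands and targets had a median of -0.044 (adjusted p = 0.378), with Id4 at -0.62 ± 0.11 and Bmp6 at 0.48 ± 0.015. Hedgehog pathway genes had a median of 0.011 (adjusted p = 0.786), and Foxf1 was the member that fell. Retinoic acid pathway genes had a median of -0.034 (adjusted p = 0.417), with the retinoic acid hydroxylases Cyp26a1 at -0.83 ± 0.018 and Cyp26b1 at 0.38 ± 0.10. Notch pathway genes had a median of 0.055 (adjusted p = 0.0877), with Hey2 at 0.75 ± 0.017 and Heyl at 0.58 ± 0.085. In FGF, PDGF and TGF-beta signalling the median was 0.034 (adjusted p = 0.786), with Inhba at 0.64 ± 0.27, Fgf7 at -0.51 ± 0.0046, Etv5 at 0.46 ± 0.057 and Pdgfc at -0.44 ± 0.099.

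Collagens had a median of 0.030 (adjusted p = 0.463) and Col8a1 rose, at 1.00 ± 0.19 (SD, n = 2 pairs). Other extracellular matrix genes had a median of 0.077 (adjusted p = 0.837), with Spon1 at -1.11 ± 0.090, Aspn at -0.57 ± 0.044, Lox at 0.44 ± 0.15 and Vcan at -0.38 ± 0.026. Another Vcan probe gave -0.073 and another Lox probe 0.29, neither past the threshold. The cartilage list had a median of -0.24 (adjusted p = 0.113), or -0.016 without a filter on dim probes, with Col9a3 at -0.54, Cnmd at 0.51, Col2a1 at -0.50 and Col9a1 at -0.41. Skeletal muscle had a median of -0.14 (adjusted p = 0.113), or -0.29 with the processed signals, with Myh3 at -0.34 and Ttn at -0.29, neither of which passed. Erythroid genes had a median of 0.21 (adjusted p = 0.0624), or 0.10 with each probe counted by itself, with Hbb-b1 at 0.43 ± 0.11. The p53 targets and apoptosis list had a median of -0.0090 (adjusted p = 0.786) while its set test pointed upwards, and Bax rose, at 0.42 ± 0.12.

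No gene passed in the lists that follow. For proliferation the median was -0.0026 (adjusted p = 0.918) while the set test pointed upwards, with Pcna at -0.14 and Top2a at 0.13. For CDK inhibitors it was -0.054 (adjusted p = 0.786), with Cdkn1a at 0.25 and Cdkn2b at -0.22, where a dimmer probe for Cdkn2b gave 0.092. For other T-box genes it was 0.11 (adjusted p = 0.624), with Tbx4 at 0.37 and Tbr1 at -0.30. For hypoxia and glycolysis it was -0.016 (adjusted p = 0.624), with Hk2 at -0.31 and Egln3 at -0.25. For the nephron lineage it was -0.00023 (adjusted p = 0.389) while the set test pointed upwards, with Six2 at 0.38 ± 1.02 (SD, n = 2 pairs) and Wt1 at 0.38 ± 0.58. For gonad, adrenal and mesonephric duct it was 0.0022 (adjusted p = 0.837), with Dhh at 0.11 and Cyp11a1 at -0.045.

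**Figure D3:**
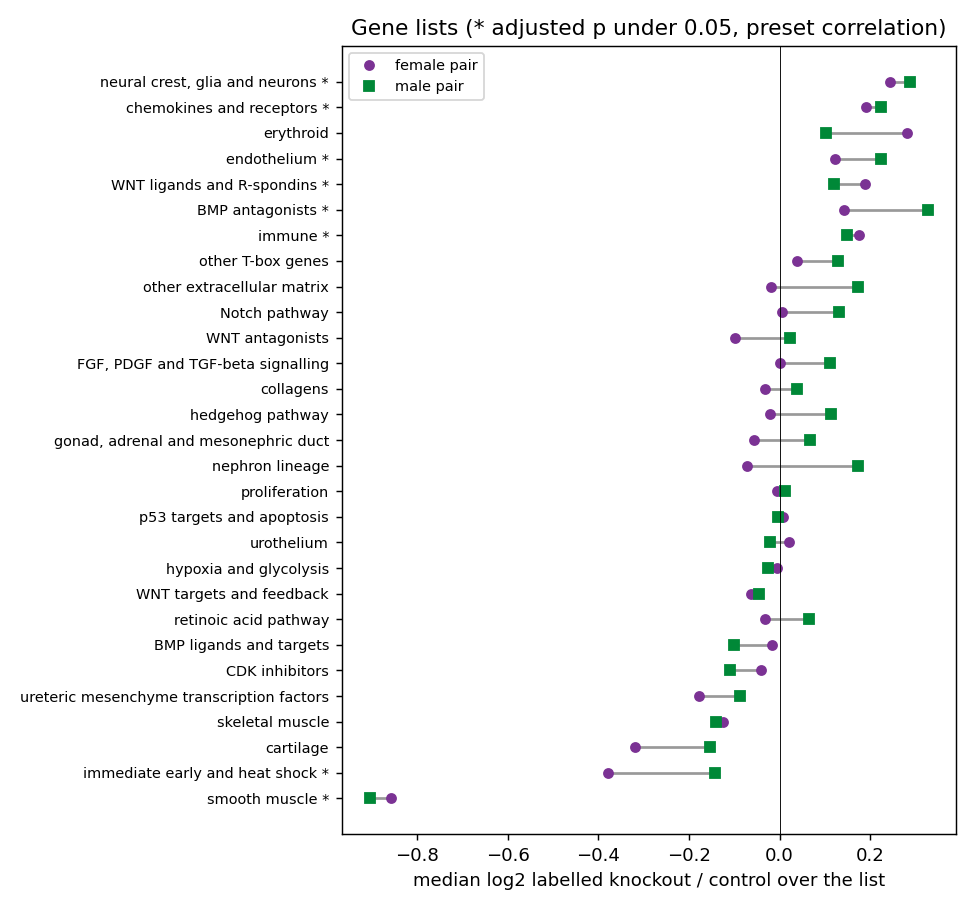
Median log2 labelled knockout over control of each of the 29 gene lists tested, in the female pair (circles) and the male pair (squares), with an asterisk on the 8 lists that passed with the preset correlation. The smooth muscle list lies apart from the others, at -0.86 in the female and -0.90 in the male pair.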

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

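The values in this part are gene and list values that pointed in opposite directions in the female and the male pair. With 1 pair per sex the differences were not tested, and dye orientation differs between the pairs as well as sex. Among named genes, Six2 was at -0.34 in the female and 1.11 in the male pair, a difference of 1.44 (male minus female). Wt1 was at -0.032 and 0.79, a difference of 0.82. The endothelial gene Egfl7 was at -0.20 and 0.85, a difference of 1.06. Cyp11a1 was at -0.095 and 0.0041, a difference of 0.10.

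Among the 29 lists, 10 had medians of opposite sign, and none of these 10 lists passed as a set. The difference between male and female pair was 0.24 for the nephron lineage, 0.19 for other extracellular matrix, 0.13 for the hedgehog pathway and 0.12 for gonad, adrenal and mesonephric duct. It was 0.12 for WNT antagonists, 0.10 for the retinoic acid pathway, 0.071 for collagens and 0.019 for proliferation. It was -0.011 for p53 targets and apoptosis and -0.041 for urothelium.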

How the results depend on the processing

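With the scanner software's processed signals, 249 genes were higher, 214 lower, 68 at least 2-fold higher in both pairs and 3 at least 2-fold apart in opposite directions. With median centring, 114 were higher, 128 lower and 6 in opposite directions, and with the deposited values 142 were higher, 143 lower and 3 in opposite directions. At an adjusted p under 0.1, 606 were higher and 544 lower. At a 1.5-fold limit, 111 were higher in both pairs, 140 lower and 26 in opposite directions. The other alternatives left 334 to 541 genes higher and 356 to 499 lower. From 1 pair alone, 56 genes were at least 2-fold higher whichever pair was left out, and 64 to 71 were at least 2-fold lower. A count in opposite directions, an adjusted p and a set test cannot be had from 1 pair. The causes of these moves were not tested.

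With cameraPR, the alternatives gave 8 to 10 shifted lists. With camera and an estimated correlation the count was 0, and the smallest unadjusted p was above the threshold too. That test rests on the arrays' 1 residual degree of freedom, so its count of 0 cannot decide whether the lists shifted. The estimated correlation was under the preset 0.01 for smooth muscle (-0.039), BMP antagonists (-0.026), WNT ligands and R-spondins (-0.091) and immune genes (-0.077). A higher correlation is therefore not why these lists lost the call. It was above the preset for the chemokine (0.345), endothelium (0.121), neural (0.150) and immediate early (0.733) lists. For these lists the p-values from cameraPR with the preset correlation may be too small, most of all for immediate early genes. Without passing, the set test for gonad, adrenal and mesonephric duct turned downwards with median centring (median 0.0088) and without a filter on dim probes (0.0012). By percentile among 10000 random lists matched on intensity, that list (47.4), WNT targets and feedback (21.9) and p53 targets and apoptosis (40.6) lay below the middle while their set tests pointed upwards. Other lists that did not pass as sets lay near the ends of the random lists. These were other extracellular matrix (100), erythroid (100) and other T-box genes (98.0) at the top. At the bottom were ureteric mesenchyme transcription factors (0), cartilage (0) and skeletal muscle (0.14). Medians near 0 also crossed 0 under some alternatives for WNT targets, p53 targets, hedgehog, proliferation, urothelium, nephron and hypoxia lists. Set tests that passed only under an alternative were erythroid and Notch genes without the filter (adjusted p = 0.0139 and 0.0313), erythroid genes with detection in both channels (0.0451), skeletal muscle with the deposited values (0.0271) and with ranks (0.0359), and ureteric mesenchyme transcription factors with each probe counted by itself (0.0120). A dimmer Cdkn2b probe gave 0.092.

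Of 73 named genes past the threshold, 35 passed under every alternative that gave them a value (Mup1, Mup18 and Grem1 had none with detection required in both channels) and 38 lost the call under 1 or more, mostly with median centring (37 genes), the deposited value table (35) or the processed signals (26). None of the 73 changed direction. Leaving out a pair moves a mean over 2 by less than its SD by construction, so those values say nothing on stability. Signal over background limits dim genes, for which 1 channel was near background.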

Other observations

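Gene groups in this part were put together after the values were seen, and all tests here were chosen then except that on neighbouring genes, planned before its value was computed. The test on tailed histone variants was planned before its value was computed too, but against the called histone genes alone, a bar that it met. That bar and those of the interferon and S-phase tests were changed after the values were seen. They went from the called members to the median of all members. Under the earlier bars, the values had counted against an interferon response and against fewer cells in S phase. The bar of the test on shared Mup signal was loosened after its value had counted against that explanation. Of 22 genes of the sarcomere and striated muscle 10 were lower and 0 higher, with Acta1 at -2.06, Sh3bgr at -1.81, Asb2 at -1.58 and Actc1 at -1.26. With the deposited values 6 were lower. Of these 22 genes, Tnnt2 is also in the smooth muscle list and Tnnc2 and Tnni1 are in the skeletal muscle list. Among 15 genes of intercalated cells, the acid-secreting cells of the collecting duct, 8 were higher and 0 lower, with the V-ATPase subunit Atp6v0d2 at 0.85 (control channel well above background on 1 of 2 arrays), the transcription factor Foxi1 at 0.76 and the ammonia transporter Rhcg at 0.66. Their median was 0.49 and was up to 0.71 under other scalings, where at least 5 were higher, and Slc4a1 is also an erythroid gene. The 7 intercalated genes that did not pass ranged from Slc4a9 at -0.11 to Rhbg at 0.34, with Car2 at -0.092 and Atp6v0a4 at 0.039. Among 11 genes of principal cells and collecting duct 2 were higher and 1 lower, but 0 passed with median centring, the processed signals or the deposited values, and Aqp2 was at 0.053. Of 10 liver genes, Afp, at -0.75, and Alb, at -0.68, were lower (1 of the 10 genes with the deposited values), and Cyp2e1 was higher.

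At a 1.5-fold limit, 26 genes differed in opposite directions in the 2 pairs, and in 25 of them the red channel was brighter on both arrays, among them Krt16, Neurog3 and Ulk1. Hes5, at -0.86 in the female and 1.69 in the male pair, was the exception.

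Of 10 Gbp genes 4 were higher (2 with the deposited values), and of 8 Mup genes 7 were higher, while Mup21 was at 0.048. DNA of another strain carried along with the targeted alleles is argued against only in that it would not hold these genes. Of the 11 rising genes, 0 lie on the chromosomes of Tbx2, Tbx3 or Tbx18. Similar copies of a family are not independent, so the 11 genes count as fewer than 11 observations. Their chromosomes were fixed before the test, which covers only DNA on the chromosomes of those loci. An effect of such DNA on genes of other chromosomes was not tested. An interferon response, which raises Gbp genes, cannot be told apart from other causes, since 25 other interferon-stimulated genes had a median of 0.076 (SD 0.324) against 0.26 for all 10 Gbp genes (0.093 and 0.57 with the processed signals) and 1.79 for the 4 called ones, with Xaf1 at 0.79, Ifi35 at 0.46 and Iigp1 at -1.07. Signal shared between near-identical Mup copies cannot be told apart from a rise of each, since probe sequences were not compared and the spread of the log2 fold changes (SD 0.69, median 1.41, or 2.81 with the processed signals) rests on copies near background in the controls. A strain difference elsewhere in the genome and an effect of the deletion stay open, as untested.

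Of 37 replication-dependent histone genes, whose mRNA has no poly(A) tail, 12 were lower and 0 higher, and of 9 non-coding RNAs without a tail 5 were lower, with Rnu2-10 at -1.24 and Rnu1b6 at -1.17. With median centring and with the deposited values, 3 of the histone genes passed, and 3 and 4 of the non-coding RNAs. Fewer cells in S phase cannot be told apart from other causes, since 17 S-phase genes had a median of -0.071 (SD 0.0667, or -0.043 with median centring) against -0.17 for all 37 histone genes and -0.58 for the 12 called ones. None of the 17 S-phase genes passed. The proliferation list, fixed before the data were examined, had a median of -0.0026 (cameraPR, adjusted p = 0.918), and 0 of its 24 genes passed. Less capture of untailed RNA from the knockout ureters cannot be told apart either, since 9 histone variants with a tailed mRNA had a median of -0.087 (SD 0.101, or -0.030 with median centring), between no change and the median of the 37. An effect of the deletion on these genes stays open, as untested.

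Beside the 6 of 18 neural genes that were higher, 2 of 3 measured genes of HOX groups 12 and 13 were higher, Hoxd13 at 0.99 and Hoxa13 at 0.86, and no set test was run on the HOX genes. A lower share of smooth muscle would raise all other cell types alike. The medians of the neural list (0.28) and the urothelium list (-0.014) differed by 0.29, at p = 0.00033 in a two-sided permutation test over genes. Genes are not independent, and this pair of lists was chosen after its values were seen, which the p-value does not allow for. By this pair the rise was not alike. The medians of endothelium (0.19), immune (0.15) and erythroid (0.21) genes lie above 0 as that explanation predicts, so a lower share of smooth muscle is not decided. Whether the knockout samples held more tissue from the posterior end of the ureter cannot be told apart from other causes. The remaining gene, Hoxd12, did not pass and lay 0.42 above the median of groups 9 to 11. An effect of the deletion on these genes stays open, as untested.

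A hypothesis of a different kind concerned DNA of another strain around the targeted alleles, since the ureters labelled knockout carry the Cre allele at Tbx18 and the controls do not. Of the 50 tested genes nearest to Tbx18 (25 on each side), 7 were called, which is 14% against 4.04% elsewhere (one-sided Fisher's exact p = 0.0039, adjusted p = 0.0117 over 3 loci). They include Tpbg at -1.06, Nt5e at -1.15, Snap91 at -0.72, Prss35 at 0.79 and Plscr4 at 0.92. Next to Tbx2, 4 of 50 were called, and next to Tbx3, 2 of 50 (adjusted p = 0.218 and 0.609). The values next to Tbx18 may come from such DNA, but an effect of the inserted Cre on its surroundings was not tested.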
